A study of Mus musculus with 12 samples.

How the data were processed

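The series holds 12 samples of mouse aortic endothelial cells, 8 for ATAC-seq and 4 for CUT&Tag of the histone mark H3K27ac. The 4 H3K27ac samples were not analysed here. The 8 ATAC-seq samples were assigned by their titles to the 4 groups that the series' design text names, 2 samples per group. The diets are abbreviated in the labels as CD and WD, and the series' title speaks of a maternal high-fat diet; M was read as the mothers and O as the offspring.

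Each group had 1 peak list in the narrowPeak format. Whether its 2 samples were pooled before peak calling is not given in the sources used here, and no list separates the samples. The submitters' processing notes name FastQC 0.12.1, Trim Galore 0.6.10, Bowtie2 2.4.5, SAMtools 1.13, deepTools 3.5.4 and MACS2 2.2.9.1, and the genome build GRCm38 (mm10), without their order or settings. Whether read ends were shifted for the transposase is not given in the sources used here. The fold enrichment of each peak over its local background, a ratio, was used as deposited. The −log10 p and −log10 q values of each peak were likewise those the authors deposited. These scores are the authors' own. As they stand they were used to describe, rank or filter peaks within a list, and the fold enrichment and −log10 p also served to recover pileups, which were compared between lists. A rank in 1 list and a rank in another list of different length show no change. The lowest −log10 q of the lists was 1.30 to 1.31, near the value of a q threshold of 0.05. No list of artefact-prone regions was applied here.

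Read counts per sample were not used here. As a measure of depth, the whole number of reads piled up at each summit was recovered from the fold enrichment and −log10 p, under the rule that MACS2 tests the pileup against a Poisson background and adds 1 read to both in the fold. A whole number matched both values within a relative tolerance of 0.0001 for 100% of peaks, and with the tail begun 1 read lower for at most 1.63%. The lowest background among peaks of a list was taken as the genome background, and the pileup behind a call in another list was worked out from the lowest −log10 p of that list.

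Peaks with several summits were counted once, and peaks on chromosome Y were left out of the comparisons. Peaks were called shared when they overlapped by at least 1 bp (bedtools 2.31.1). The 4 comparisons were WDM-CDO against CDM-CDO and WDM-WDO against CDM-WDO for the diet of the mothers, and CDM-WDO against CDM-CDO and WDM-WDO against WDM-CDO for that of the offspring. A region counted as added when it was in the first list only, and as lost when it was in the second only. For the comparison across offspring diets, the peaks of all 4 lists were merged into 48003 regions; the 2 maternal comparisons share no list.

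Genes were the 21631 protein-coding genes of chromosomes 1 to 19 and X in a RefSeq table of GRCm38.p6, which gives the span of each gene without its strand. The plan called for distances to transcription start sites. These were replaced by a window of 1 kb on both sides of both gene ends, called a gene-end peak, and by the nearest gene span within 100 kb for the assignment of regions. The ends are named by coordinate, as the lower-coordinate or upper-coordinate end, so an end is not known to be a promoter. Sequence was not used here, so the planned motif shares were not computed.

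In total 22 gene lists with 394 members were fixed before the data were examined, along with the comparisons and the first set of alternatives; 391 members matched the table and Mx1, Mx2 and Ahsp did not. No gene was in more than 1 list. The lists were endothelial identity, shear stress and nitric oxide, adhesion and chemokine genes of activated endothelium, the NF-kB pathway, AP-1 subunits and early response genes, interferon response, antigen presentation, cholesterol synthesis and uptake, cholesterol export and oxysterol handling, fatty acid handling, oxidative stress response, endothelial to mesenchymal transition and TGF-beta, Notch and angiogenesis, and histone acetylation and methylation enzymes. The others were housekeeping genes and markers of smooth muscle cells, fibroblasts, macrophages and monocytes, lymphocytes, neutrophils, red cells and adipocytes. For each list, the share of assigned regions that were added or lost was placed as a percentile among 10000 random gene lists of the same size, matched on the number of regions per gene, with ties counted to equal parts on both sides. A percentile outside the central 95% is a description of these lists and not a test of the diets. The random lists were not matched on the strength of peaks or their place at gene ends. Lists rich in strong gene-end peaks, which were mostly shared, can therefore have few added and few lost regions under any diet.

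The genes named were chosen by a rule fixed in advance. For each comparison and direction they were taken, in order of −log10 q in their own list, from the 10 genes with the strongest gene-end peak where the other list had no peak at that end. For the maternal comparisons the 10 strongest unshared peaks over 1 kb from gene ends were added. From each gene list came at most 4 members per direction whose gene ends differed, by the same order, and at most 2 with the most unshared regions. Some genes that the rule would name are not reported here. Genes of the closing section outside this rule are named there as chosen later.

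The alternatives fixed then were a −log10 q of at least 5, lists shortened to the length of the shortest by −log10 q or by fold enrichment, the stronger 50% of a list against the other in full, reciprocal overlap of 50%, no peak of the other list within 500 bp, autosomes only, gene ends within 2500 bp, and assignment within 10 kb. Further alternatives were chosen after the data were seen. They were the 10000 strongest peaks of a list against the other in full, unshared peaks expected at 2 or more times the pileup needed for a call in the other list, and the ratio of recovered pileups at gene ends called in both lists. For the expected pileup, pileups above background were scaled by the median ratio at shared peaks of the stronger 50%. The first form of this alternative scaled whole pileups, background included. It was replaced after its values were seen, and both forms are reported.

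The overlap counts, the pileup recovery and the list percentiles were tested on simulated data. All 200 planted unshared peaks per direction were recovered in each comparison, as were 4953 of 4953 simulated pileups, and 6 of 100 unchanged gene lists fell outside the central 95%. The planted peaks were put where the other list had none, so their recovery checks the counting only. Unchanged lists had a common chance of an added region, so they do not show how percentiles behave where regions differ in strength and place. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.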

Results

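Open chromatin was mapped by ATAC-seq, in which a transposase cuts and tags accessible DNA, in aortic endothelial cells (MAECs) of mice. These cells line the vessel wall in which atherosclerotic plaques form. The 8 ATAC-seq samples fell into 4 groups of 2, named by the diet of the mothers (CDM or WDM) and the diet of the offspring (CDO or WDO). The offspring of the WDO groups had been returned to WD for 4 weeks before their cells were taken. Each group was represented by 1 peak list, so there were no replicates to compare and no difference between groups carries a p-value. Intervals on shares are 95% Wilson intervals, and they cover counting error only.

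The lists held 22178 peaks for CDM-CDO, 28319 for WDM-CDO, 18962 for CDM-WDO and 26275 for WDM-WDO on chromosomes 1 to 19 and X. They covered 15.3, 19.2, 11.5 and 17.4 Mb. Genome background was near 4.84, 5.59, 5.49 and 6.08 reads, and the median pileup at peak summits was 36, 38, 31 and 39. A peak within 1 kb of either end of a protein-coding gene was present for 10404 of 21631 genes in CDM-CDO (48.1%), 11068 in WDM-CDO (51.2%), 8685 in CDM-WDO (40.2%) and 10292 in WDM-WDO (47.6%). Housekeeping genes, which nearly all cells use, had such a peak at 20 of 20 members in both CDO lists, 17 in CDM-WDO and 18 in WDM-WDO. AP-1 and early response genes, which include the Fos and Jun families, had such a peak at 19, 19, 17 and 19 of 22 members. The NF-kB pathway, the main route of inflammatory signalling, had 17, 19, 18 and 18 of 22. Of the housekeeping genes, Actb lacked a gene-end peak in both WDO lists, but a peak further inside it was called in every list.

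Of the 22 gene lists, those of white blood cell markers differed most between the groups at gene ends. Macrophage and monocyte markers carried a gene-end peak at 5 of 16 members in CDM-CDO, 5 in WDM-CDO, 4 in CDM-WDO and 12 in WDM-WDO. Lymphocyte markers carried one at 8, 9, 2 and 6 of 16 members, and neutrophil markers at 0, 0, 1 and 4 of 12. Endothelial identity genes, which encode junction proteins, receptors and transcription factors typical of these cells, carried one at 7, 9, 7 and 6 of 20. These shares (35%, 45%, 35% and 30%) lay below those of all protein-coding genes in each list, though within counting error. Lymphocyte markers lay above all genes in both CDO lists (50% and 56.25%), also within counting error. Macrophage and monocyte markers lay above all genes in WDM-WDO only (75%, 50.5 to 89.8%, against 47.6%). Smooth muscle markers carried a gene-end peak at 5, 5, 2 and 2 of 14, and fibroblast markers at 2, 4, 2 and 3 of 14.

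**Figure D1:**
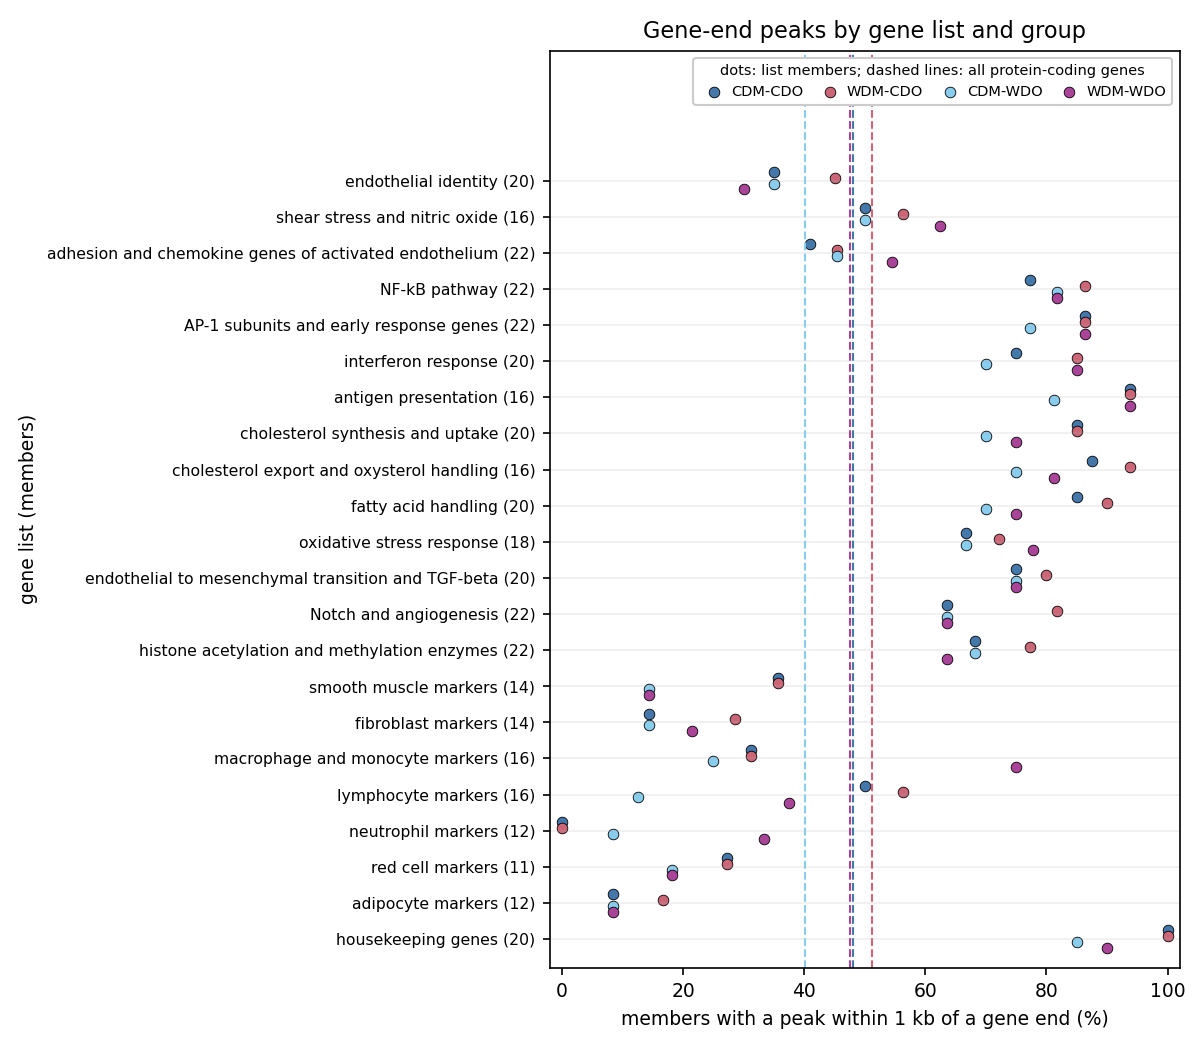
Share of the members of each gene list (in percent, members in parentheses) with a peak within 1 kb of either gene end, with 1 dot per group and dashed lines for all 21631 protein-coding genes in that group. Macrophage and monocyte markers stood at 12 of 16 in WDM-WDO against 4 or 5 in the other lists, and lymphocyte markers at 2 of 16 in CDM-WDO against 6 to 9.

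The first comparison asked how the diet of the mothers marked the chromatin of offspring kept on CD. In WDM-CDO, regions near endothelial identity genes were often present without a counterpart in CDM-CDO. They made up 33 of 63 regions near these genes (52.4%), against 32.3% of all regions, the 98.9th percentile among random gene lists. Cdh5, which encodes the junction protein VE-cadherin, had 6 regions in WDM-CDO and 1 in CDM-CDO, and the ETS transcription factor gene Erg had 7 and 1. Regions near fibroblast markers were also present in WDM-CDO alone, 11 of 17 (64.7%, 99.8th percentile), led by the collagen gene Col1a1 and the actin-severing protein gene Gsn with 2 each. Regions near antigen presentation genes were rarely added in WDM-CDO, 4 of 37 (10.8%, 0.06th percentile). Housekeeping genes had as low a share (3 of 37, 0.06th percentile), and 15 of 16 antigen presentation genes had a gene-end peak in both lists. The random lists were not matched on peak strength or place. Low shares, here and in the comparisons below, may therefore reflect strong gene-end peaks rather than diet.

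At gene ends, WDM-CDO had a peak that CDM-CDO lacked at 1077 genes, CDM-CDO one that WDM-CDO lacked at 413, and 9991 genes had one in both. Here and below an end is termed open in a list where a peak was called, so an end without a call is not shown to be closed. Among endothelial identity genes the ends open in WDM-CDO alone were those of Cldn5, the claudin of endothelial tight junctions (−log10 q of 7.58), and of the adhesion molecule gene Esam (6.87). Edn1, which encodes the vasoconstrictor endothelin-1 (16.1), and the caveolin gene Cav1 (3.79) were open in WDM-CDO alone among shear stress and nitric oxide genes. Of the Notch and angiogenesis genes, 4 were open in WDM-CDO alone: Esm1 (9.49), the Notch ligand gene Dll1 (5.55), the lymphatic growth factor gene Vegfc (4.02) and the apelin receptor gene Aplnr (1.85). Their summit pileups were 33, 37, 21 and 21 reads, and that of Cav1 was 24. Pileups above background at strong shared peaks were a median 0.685 times as high in CDM-CDO, where the lowest called pileup was 14. For the weakest of these ends, a missed call in CDM-CDO cannot be told from closed chromatin. The other members open in WDM-CDO alone included Srebf1, a regulator of lipid synthesis (16.0), the NF-kB cofactor gene Bcl3 (16.6), the glutathione synthesis gene Gclc (9.43), the histone acetyltransferase gene Kat6a (15.1) and the T cell kinase gene Lck (12.8). The cytokine gene Tnf (13.2) and the endothelin receptor gene Ednrb (4.04) were open in CDM-CDO alone. Abca1, the exporter of cellular cholesterol, had 11 regions in WDM-CDO and 5 in CDM-CDO, with 6 present in WDM-CDO alone.

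Of all genes, the strongest ends open in WDM-CDO alone were those of Gm527 (chromosome 12, 64917659 to 64917984, −log10 q of 61.0), the histone H3 methyltransferase gene Dot1l (chromosome 10, 80754946 to 80755332, 35.1) and Bahcc1 (34.8). The strongest open in CDM-CDO alone was H2-Ab1, a class II antigen presentation gene (chromosome 17, 34268634 to 34269371, 63.3), followed by the ubiquitin protease gene Usp12 (21.8). Away from gene ends, the strongest peak of WDM-CDO alone lay within Parvb, which encodes a focal adhesion protein (chromosome 15, 84235482 to 84236003, 42.7). The next lay 16517 bp from Rgs16, a brake on G protein signalling (chromosome 1, 153723315 to 153723836, 33.5). The strongest of CDM-CDO alone lay among the V segments of the immunoglobulin kappa chain (chromosome 6, 70074034 to 70074324, 73.8), 691396 bp from the nearest protein-coding gene.

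In numbers, 11553 of the 28319 WDM-CDO peaks had no counterpart in CDM-CDO (40.8%, interval 40.2 to 41.4%), and 5356 of the 22178 CDM-CDO peaks had none in WDM-CDO (24.2%, 23.6 to 24.7%). Peaks on 1 side only were mostly weak, with 1045 and 113 of them in the stronger 50% of their list, and mostly away from gene ends. Gene-end peaks made up 11.3% and 10.8% of them, against 53.5% and 53.3% of shared peaks, and among the strongest 10% of each list 0 of 2832 and 2 of 2218 were unshared. With both lists at equal length, 3862 and 3817 peaks were unshared, and with peaks limited to those expected at 2 or more times the pileup that a call needed in the other list the order turned, at 39 for WDM-CDO and 208 for CDM-CDO, an order that the scaling of pileups by 0.685 and 1.41 itself favours.

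Further lists stood outside the central 95% of random lists in this comparison. Neutrophil markers had 3 of 4 regions and adipocyte markers 8 of 13 in WDM-CDO alone (98.3rd and 98.0th percentile). AP-1 and early response genes had 19 of 78 (24.4%, 1.995th percentile) and housekeeping genes 3 of 37 (8.11%, 0.06th). Regions in CDM-CDO alone were rare near adhesion and chemokine genes (0 of 28, 1.07th percentile), cholesterol synthesis genes (0 of 26, 1.72th), cholesterol export genes (2 of 56, 0.46th) and fatty acid handling genes (1 of 56, 0.05th), against 13.7% of all regions. The calls for neutrophil markers, adhesion genes and both cholesterol lists were lost with assignment within 10 kb, at equal list length and with a stricter threshold, wherever these gave a value. Those for adipocyte markers, AP-1 genes and housekeeping genes held under 1 of these 3 alternatives, and that for fatty acid genes under 2.

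**Figure D2:**
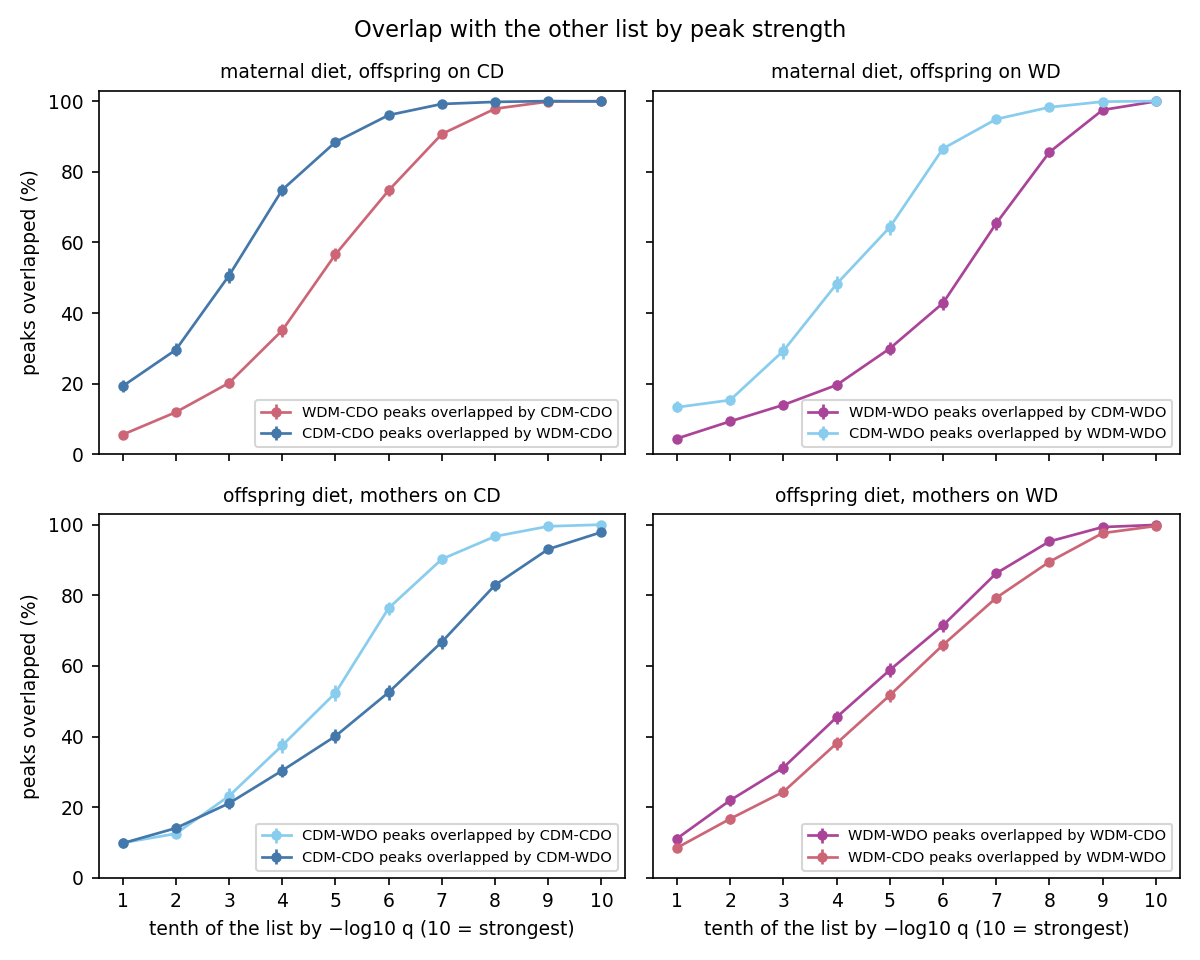
Share of peaks (percent, with 95% Wilson intervals) overlapped by the other list of each pair, by strength within the own list in steps of 10% (1 weakest, 10 strongest, by −log10 q). In every panel the share rose with strength, except between the 2 strongest steps of CDM-CDO against WDM-CDO (2219 of 2219, then 2216 of 2218), and among the strongest 10% at most 47 of 2218 peaks were unshared.

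The second comparison asked the same of offspring returned to WD. Regions near macrophage and monocyte markers were present in WDM-WDO and absent from CDM-WDO at 26 of 37 (70.3%), against 42.8% of all regions, the 99.93rd percentile among random lists. At gene ends, 8 of the 16 macrophage and monocyte markers were open in WDM-WDO alone. These were led by the lipid receptor gene Trem2 (−log10 q of 11.1), the complement gene C1qb (10.1), the Fc receptor gene Fcgr1 (8.97) and the macrophage growth factor receptor gene Csf1r (5.92). Regions near lymphocyte markers followed, with 16 of 23 in WDM-WDO alone (69.6%, 99.6th percentile). Endothelial identity genes went the other way, with 25 of 58 regions in CDM-WDO alone (43.1%, against 15.9% of all regions, 99.98th percentile) and 16 of 58 in WDM-WDO alone (27.6%, 0.045th).

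Among endothelial identity genes, the ends of Cldn5 (4.38) and of the transcription factor gene Sox7 (4.16) were open in CDM-WDO alone, and that of the adhesion molecule gene Icam2 in WDM-WDO alone (8.85). Cdh5 and Cldn5 each had 3 regions in CDM-WDO alone. Fli1, an ETS factor gene, and Kdr, the main receptor gene for vascular endothelial growth factor, each had 3 in WDM-WDO alone. Notch and angiogenesis genes had 17 of 57 regions in WDM-WDO alone (29.8%, 0.865th percentile), and Nrp1, a coreceptor gene of this group, had 3 in CDM-WDO alone.

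Itgam, which encodes a myeloid integrin, had 6 regions in WDM-WDO and 1 in CDM-WDO, and Mertk, a receptor gene for uptake of dead cells, had 4 and 1. The lymphocyte markers open at an end in WDM-WDO alone were Il7r (24.2), Cd3g (7.99), Cd4 (5.54) and Cd79a (2.27). Neutrophil markers had 6 of 8 regions in WDM-WDO alone (97.58th percentile, a call kept under 1 of 3 alternatives), with gene-end peaks of Csf3r (6.98), Mmp8 (2.42) and Retnlg (2.32). Of the lipid genes, Abca1 had 18 regions in WDM-WDO and 8 in CDM-WDO, with 11 in WDM-WDO alone, and Pparg, a lipid-sensing transcription factor gene, had 7 and 1. Cd36, the scavenger receptor gene for oxidised lipoprotein and fatty acids, had 4 regions in CDM-WDO alone. Interferon response genes open in WDM-WDO alone were Oas2 (14.1), Ifit1 (11.4) and Rsad2 (10.7), and the nitric oxide synthase gene Nos3 (15.1), the chemokine gene Cxcl10 (9.77), the AP-1 gene Batf (13.7), the class I regulator gene Nlrc5 (12.5) and the sterol desaturase gene Sc5d (19.9) were open there alone.

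Tnfaip3, which encodes a brake on NF-kB, had 14 regions in WDM-WDO and 7 in CDM-WDO. Near NF-kB genes as a whole, 4 of 79 regions were in CDM-WDO alone (1.06th percentile). AP-1 and early response genes had fewer one-sided regions than random lists in both directions, 29 of 82 in WDM-WDO alone (0.615th percentile) and 3 of 82 in CDM-WDO alone (0.24th). So did antigen presentation genes, with 9 of 35 and 1 of 35 (1.07th and 2.36th percentile), and housekeeping genes in WDM-WDO alone, with 8 of 34 (2.48th). Random lists were not matched on peak strength or place, so such low shares may reflect strong gene-end peaks rather than diet. With a stricter peak threshold the antigen presentation value for CDM-WDO moved to the 58.01st percentile.

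Of all genes, the strongest ends open in WDM-WDO alone were those of the cohesin acetyltransferase gene Esco2 (chromosome 14, 65833708 to 65834180, 46.2), the autophagy protease gene Atg4d (45.0) and the splicing factor gene Snrpc (44.2). The strongest in CDM-WDO alone were those of Zcchc14 (chromosome 8, 121652866 to 121653248, 25.7) and the zinc exporter gene Slc30a1 (23.0). Away from gene ends, the strongest peaks in WDM-WDO and not in CDM-WDO lay 1035295 bp from Lrrc4c (chromosome 2, 98666967 to 98667301, 314) and 21210 bp from the monocyte antigen gene Ly6c2 (chromosome 15, 75086693 to 75086951, 213). The peak far from Lrrc4c had 737 reads at a fold of 6.21, and the peak near Ly6c2 had 331 reads at a fold of 10.8. The local background of each was thus far above the genome background of 6.08 reads, and artefact-prone regions were not filtered out. Neither peak can therefore be told from an artefact. In CDM-WDO alone, peaks lay 13735 bp from Ssu2 (21.1), 6177 bp from Fgd5, an exchange factor gene active in endothelium (chromosome 6, 91972160 to 91972650, 20.4), and 56193 bp from the Notch target gene Hes1 (chromosome 16, 30008567 to 30009164, 19.1).

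In numbers, 13967 of 26275 WDM-WDO peaks had no counterpart in CDM-WDO (53.2%, 52.6 to 53.8%) and 6678 of 18962 CDM-WDO peaks none in WDM-WDO (35.2%, 34.5 to 35.9%). Gene-end peaks were open in WDM-WDO alone at 2070 genes, in CDM-WDO alone at 463 and in both at 8222. At equal list length 7290 and 7294 peaks were unshared. Limited to peaks expected at 2 or more times the calling pileup, the order turned, at 62 for WDM-WDO and 336 for CDM-WDO. The scaling of pileups by 0.637 and 1.48 itself favours this order.

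**Figure D3:**
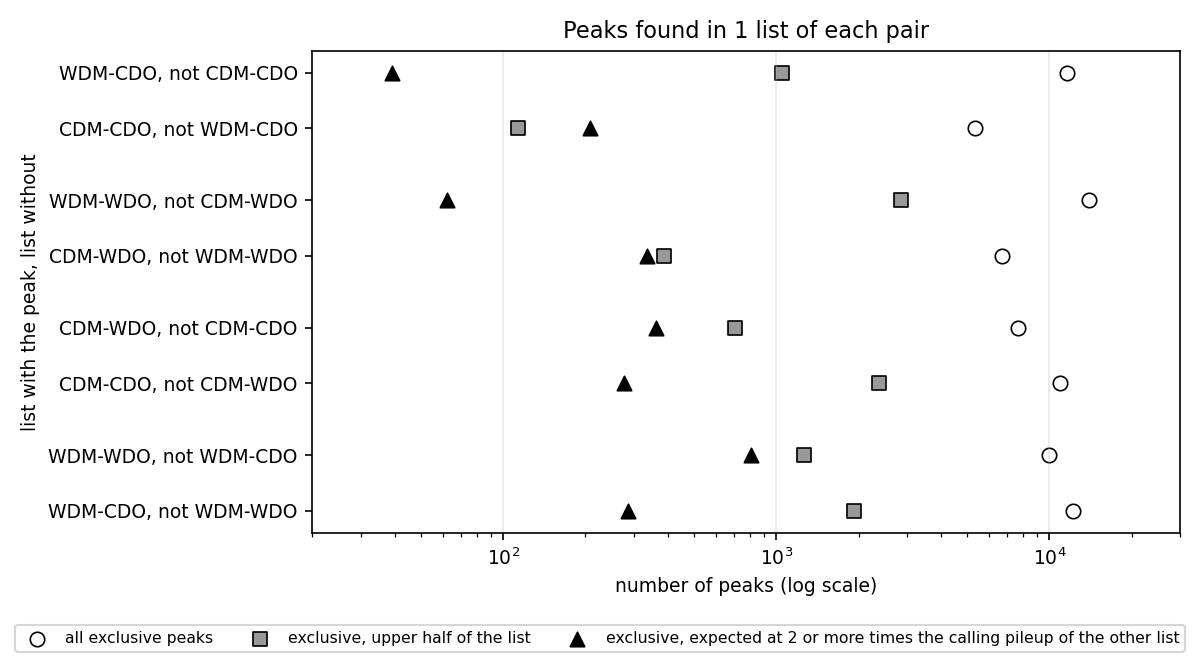
Number of peaks (log scale) found in 1 list of each pair and not in the other. Circles give all such peaks, squares those in the stronger 50% of their own list, and triangles those expected at 2 or more times the pileup that a call needed in the other list. The lists of WD mothers led by circles and squares and trailed by triangles when set against the lists of CD mothers. The scaling of pileups between lists favours this order of triangles by construction.

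Regions that followed the mothers' diet under both offspring diets were counted over 48003 merged regions. In the lists of WD mothers alone under both offspring diets there were 1691 regions, and in those of CD mothers alone 234. Opposite directions were seen at 614 regions, in WDM-CDO and CDM-WDO alone, and at 503, in CDM-CDO and WDM-WDO alone. Independent lists of these sizes would share 3299, 733, 1582 and 1528 regions. All 4 counts lay below these values, in same and opposite directions alike. The merged regions leave out every region that is in no list, which raises such values by construction. The shortfall is therefore no sign that the regions avoid one another. The odds ratio of the 4 counts, same directions over opposite ones, was 1.28. With equal list lengths the odds ratio was 2.09, with 769 regions in the lists of WD mothers alone, and with a stricter peak threshold it was 0.767, with 23 regions in the lists of CD mothers alone. All 4 lists shared 10351 regions (21.6%), and 8520 were found in WDM-WDO alone, 8190 in WDM-CDO, 5243 in CDM-WDO and 4420 in CDM-CDO.

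The third comparison set CDM-WDO against CDM-CDO, and so asked about the offspring's own diet where the mothers had CD. Regions near lymphocyte markers were present in CDM-CDO and absent from CDM-WDO at 23 of 30 (76.7%), against 36.2% of all regions, above every one of 10000 random lists. At gene ends 6 of the 16 lymphocyte markers were open in CDM-CDO alone. They were led by Cd79b of the B cell receptor (chromosome 11, 106311384 to 106311905, −log10 q of 85.3), and Cd3e (27.3) and Cd3g (17.5) of the T cell receptor complex. Bcl11b and Gata3, transcription factor genes of T cells, had 5 and 3 regions in CDM-CDO alone. Regions near endothelial identity genes were added in CDM-WDO, 23 of 53 (43.4%, against 21.4% of all regions, 99.4th percentile), and lost at 11 of 53 (0.21th), with 4 regions at Cdh5 against 1 and 3 at Erg against 1.

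Esam (6.70) and Cldn5 (4.38) were open at an end in CDM-WDO alone, as were Edn1 (5.02), Cav1 (4.44) and the monocyte chemokine gene Ccl2 (5.02), while Icam2 (15.9), Erg (5.03), Nos3 (8.36) and Cxcl10 (10.8) were so in CDM-CDO alone. Lipid genes with an end open in CDM-CDO alone were Sc5d (14.9), of the last steps of cholesterol synthesis, Scap, the sterol sensor gene (12.7), the lipoprotein gene Apoe (16.2), the fatty acid transporter gene Slc27a1 (22.1), and the lipid-binding protein gene Fabp4 (8.10). Cd36 had 8 regions in CDM-WDO and 0 in CDM-CDO. The histone acetyltransferase gene Kat2b (19.98) and the Notch target gene Hey1 (13.5) were open in CDM-CDO alone. The macrophage transcription factor gene Spi1 (4.38) was open in CDM-WDO alone, and Lyz2 (5.50) and C1qa (2.92) in CDM-CDO alone.

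Losses were rare near oxidative stress genes (4 of 39, 0.01th percentile), AP-1 and early response genes (14 of 67, 0.075th), fatty acid handling genes (9 of 49, 0.085th), histone enzymes (0.695th), adhesion and chemokine genes (1.56th), Notch and angiogenesis genes (1.95th) and NF-kB genes (2.16th). AP-1 and housekeeping genes also had few added regions (1.24th and 2nd percentile). The calls for adhesion and Notch genes were lost under each of 3 alternatives. Those of few added regions near AP-1 and housekeeping genes held under 1 of the 3. Those of rare losses near fatty acid, histone enzyme and NF-kB genes held under 2.

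Of all genes, the strongest gene-end peak in CDM-CDO alone lay at the lower-coordinate end of the actin gene Actb (chromosome 5, 142903128 to 142903458, 217), a gene with a further peak inside it in all 4 lists. Next came Cd79b, the class I antigen presentation gene H2-D1 (85.0), the lymphoid surface antigen gene Ly6d (84.8), Gas7 (73.6), the actin-binding thymosin gene Tmsb4x (71.8) and the tubulin gene Tubb5 (68.1). The Cd79b peak also lay at the lower-coordinate end. Neither end is known to be a promoter, so the missing peaks do not show that the promoter of Actb or Cd79b closed. The strongest gene ends open in CDM-WDO alone were those of Tppp3 (chromosome 8, 105471268 to 105471620, 18.8), the focal adhesion gene Pxn (17.2), H2-Q7 (15.2) and the inflammasome gene Nlrp3 (chromosome 11, 59541410 to 59544049, 13.1).

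In numbers, 7648 of 18962 CDM-WDO peaks (40.3%, 39.6 to 41.0%) and 10890 of 22178 CDM-CDO peaks (49.1%, 48.4 to 49.8%) were unshared, with 435 and 2154 genes open at an end on 1 side only. Gene-end peaks made up 6.68% and 21.8% of unshared peaks. Peak names carried the label 08w in both CDO lists and 12w in both WDO lists, so the offspring's diet and this label cannot be told apart in either comparison of offspring diet. Under a stricter threshold the counts were 1551 and 5777, and limited to peaks expected at 2 or more times the calling pileup the order turned, at 363 and 277. Scaling by 1.20 and 0.768 itself favours this turn.

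The fourth comparison set WDM-WDO against WDM-CDO, the offspring's diet where the mothers had WD. Regions near macrophage and monocyte markers were added in WDM-WDO at 23 of 40 (57.5%, against 24.9% of all regions, 99.98th percentile), and those near neutrophil markers at 7 of 10 (99.97th). Regions near endothelial identity genes were lost at 36 of 69 (52.2%, against 29.7% of all regions, 99.78th percentile), near lymphocyte markers at 20 of 40 (50%, 98.9th) and near fibroblast markers at 12 of 22 (98.7th). Erg had 1 region in WDM-WDO and 7 in WDM-CDO, and Pecam1, the endothelial adhesion molecule CD31, had 1 and 6. Losses were rare near NF-kB genes, 9 of 84 (10.7%, 0.01th percentile), and near AP-1 and early response genes, 11 of 90 (0.01th). Such low shares may again reflect strong gene-end peaks, on which the random lists were not matched.

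Macrophage and monocyte markers open at an end in WDM-WDO alone were 7, led by Spi1 (12.6), Trem2 (11.1), C1qb (10.1) and Csf1r (5.92), and neutrophil markers 4, with S100a8 (10.4), Csf3r (6.98), Mmp8 (2.42) and Retnlg (2.32). Tnf (35.4) and Ccl2 (15.6) were open there alone among adhesion and chemokine genes. Endothelial identity genes open in WDM-CDO alone were Erg (7.93), Cldn5 (7.58) and Sox7 (3.14), and 5 Notch and angiogenesis genes were so, led by Esm1 (9.49), Hey1 (9) and Dll1 (5.55). Lymphocyte markers open in WDM-CDO alone were 5, led by Cd79b (48.02), Cd3e (39.2) and Lck (12.8), while Il7r (24.2) and Cd79a (2.27) were open in WDM-WDO alone. Scap (23.7), Apoe (14.3), Slc27a1 (27.6), Fabp4 (13.5) and Kat2b (27.7) were open in WDM-CDO alone, and each of these 5 genes was also open in CDM-CDO and not in CDM-WDO. Abca1 had 18 regions in WDM-WDO and 11 in WDM-CDO.

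Losses were also rare near oxidative stress genes (6 of 57, 0.04th percentile), adhesion and chemokine genes (4 of 40, 0.24th), macrophage and monocyte markers (0.55th) and interferon response genes (1.42th). Adipocyte markers had few added (2.14th) and many lost regions (97.58th), and their calls and that of the interferon genes were lost under each of 3 alternatives. The call of rare macrophage and monocyte losses held under 1 of the 3, and that of rare adhesion gene losses under 2. Over the 4 comparisons, shear stress and nitric oxide genes stayed between the 4.05th and 86.9th percentile and genes of endothelial to mesenchymal transition between the 5.74th and 63.1st. Smooth muscle markers stayed between the 37.8th and 94.1st, and red cell markers between the 28.3rd and 90.9th. In all, 48 of 176 percentiles lay outside the central 95%, where 8.8 would if the gene lists behaved as the random lists do. The random lists were not matched on peak strength or place, and many of the 48 were low shares. Strong shared gene-end peaks can bring about low shares under any diet, so the excess over 8.8 is no count of diet effects.

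Of all genes, the strongest ends open in WDM-WDO alone were those of Adamts13, the protease of von Willebrand factor (chromosome 2, 26973717 to 26974444, 33.5), Myl6b (29.1), Pxn (25.6), the coagulation factor gene F10 (23.1), Lin54 (22.0) and the costimulatory receptor gene Cd86 (chromosome 16, 36665310 to 36666113, 20.9). Those open in WDM-CDO alone were again led by Actb (158), Ly6d (81.5), Gas7 (66.7) and H2-D1 (66.0).

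In numbers, 9965 of 26275 WDM-WDO peaks (37.9%, 37.3 to 38.5%) and 12162 of 28319 WDM-CDO peaks (42.9%, 42.4 to 43.5%) were unshared, with 594 and 1370 genes open at an end on 1 side only. Limited to peaks expected at 2 or more times the calling pileup, the order turned, at 806 and 286. Scaling by 1.15 and 0.795 itself favours this turn.

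**Figure D4:**
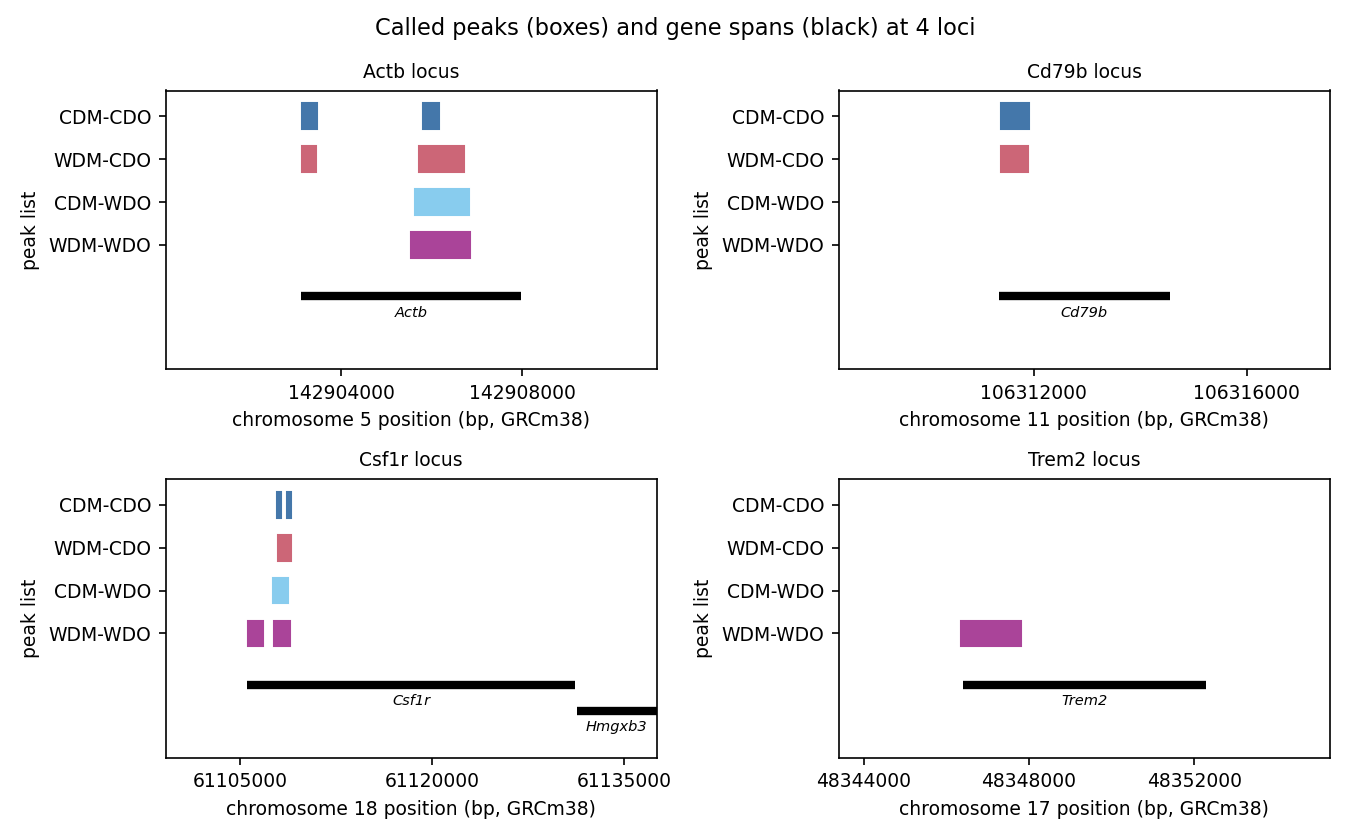
Called peaks (coloured boxes, 1 line per group) and gene spans (black bars) along the chromosome (bp, GRCm38) at 4 loci. The peak at the lower-coordinate end of Actb and the peak at Cd79b were called in both CDO lists only, while a peak at the lower-coordinate end of Csf1r and 1 at Trem2 were called in WDM-WDO only.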

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

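The comparison of list percentiles between offspring diets and between maternal diets was chosen only after those percentiles were known; the counts on chromosome Y were not part of any comparison.

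Endothelial identity genes stood out because their regions moved in opposite directions under the same contrast. With the mothers' WD against CD, regions near them were added at the 98.92nd percentile where offspring had CD and lost at the 99.98th percentile where offspring had WD. With the offspring's WD against CD, they were added at the 99.42nd percentile where mothers had CD and lost at the 99.78th where mothers had WD. These pairs rest on the same 4 lists, so they are 1 pattern seen from 2 sides, and the difference itself was not tested. Markers of other cell types moved in the same comparisons: fibroblast regions were added in WDM-CDO over CDM-CDO (99.82nd) and lost in WDM-WDO against WDM-CDO (98.67th), macrophage and monocyte regions were added in WDM-WDO (99.93rd against CDM-WDO and 99.98th against WDM-CDO), and lymphocyte regions were lost in CDM-WDO against CDM-CDO (above every random list). Cdh5 had 1 region in CDM-CDO, 6 in WDM-CDO, 4 in CDM-WDO and 3 in WDM-WDO, and Pecam1 had 1, 6, 2 and 1; both were singled out after their values were seen.

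Peaks on chromosome Y, which entered no comparison, numbered 4 in CDM-CDO, 5 in WDM-CDO and 8 in WDM-WDO, each above the limit of 3 that a count of 0 allows, and 3 in CDM-WDO.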

How the results depend on the processing

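The limits to 10000 peaks, to 2 or more times the calling pileup and to pileup ratios were tests chosen only after the results were seen. Autosomes only, reciprocal overlap of 50%, no peak within 500 bp and gene ends within 2500 bp kept every count they were applied to within 1.5 times. Unshared peak counts are given for WDM-CDO and CDM-CDO, WDM-WDO and CDM-WDO, CDM-WDO and CDM-CDO, and WDM-WDO and WDM-CDO, in this order; the cause of the changes was not tested unless stated. With the stricter threshold they were 4621 and 1122, 7189 and 878, 1551 and 5777, and 3828 and 5260. For the stronger 50% of each list against the other in full they were 1045 and 113, 2861 and 388, 705 and 2369, and 1257 and 1929. For the 10000 strongest they were 154 and 58, 1138 and 521, 901 and 1817, and 418 and 647. Limited to 2 or more times the calling pileup, where 1 scaling factor per list lowers one list and raises the other and so favours this order by construction, they were 39 and 208, 62 and 336, 363 and 277, and 806 and 286, the reverse order in each pair. With background scaled too they were 27 and 294, 42 and 495, 526 and 213, and 996 and 239. Equal length by −log10 q gave 3862 and 3817, 7290 and 7294, 7984 and 8017, and 5200 and 5308, near equal by construction. Equal length by fold gave 4646 and 4620, 7560 and 7540, 8193 and 8237, and 6027 and 6088.

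Of the regions that followed the mothers' diet under both offspring diets, 769 were in the lists of WD mothers alone at equal length, and 23 in those of CD mothers alone with the stricter threshold. List percentiles outside the central 95% numbered 48, against 28 with the stricter threshold, 34 at equal length, 39 within 10 kb and 20 of 61 by pileup ratio. Of the 48, 13 left the band within 10 kb. Calls held within 10 kb, at equal length by −log10 q and with the stricter threshold were, for mothers' diet with offspring on CD, many regions in WDM-CDO alone near endothelial and fibroblast genes, and few near antigen presentation genes. With offspring on WD they were many in CDM-WDO alone near endothelial genes, many in WDM-WDO alone near macrophage and lymphocyte markers, and few there near antigen presentation genes. For offspring diet with mothers on CD they were many in CDM-WDO alone near endothelial genes, many in CDM-CDO alone near lymphocyte markers, and few there near AP-1 and oxidative stress genes. With mothers on WD they were many in WDM-WDO alone near macrophage and neutrophil markers, many in WDM-CDO alone near endothelial, lymphocyte and fibroblast genes, and few there near NF-kB, AP-1 and oxidative stress genes. Each other call was lost under at least 1 of these 3 settings. None of these settings matched the random lists on peak strength or place, which limits the calls of few regions. The side of the median changed for cholesterol export genes (CDM-CDO alone, 72.68th percentile with the stricter threshold), neutrophil markers (WDM-CDO alone, 44.68th at equal length) and antigen presentation genes (CDM-WDO alone, 58.01st with the stricter threshold). Neutrophil markers had too few regions for a value with the stricter threshold against CDM-CDO.

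No paired analysis was possible because each group had 1 list, which carries no replicate number. For the same reason leaving out a replicate and the replicate block were not run, and the planned motif alternatives were not run without sequence. Depth per sample was not used here. Of the peaks of WD mothers alone, 47.8% and 50.4% were expected below the pileup that a call needs in the other list. These shares rest on 1 scaling factor per list, and whether depth limits these counts was not tested.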

Other observations

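The pileup ratios, the genes singled out from them and every test weighed below were chosen only after the results were seen, except the test of far gene ends against regions away from gene ends.

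At gene ends with a peak in both lists, the recovered pileups of the highest peak within 1 kb of the same end were compared as log2 ratios centred on the median of all such genes, which was 0.50 for WDM-CDO over CDM-CDO, 0.55 for WDM-WDO over CDM-WDO, −0.29 for CDM-WDO over CDM-CDO and −0.26 for WDM-WDO over WDM-CDO. The compared peaks overlapped at 98.8% to 99.3% of the genes. Of 61 list medians, 20 lay outside the central 95% of random lists, where 3.05 would if the gene lists behaved as the random lists do. The random lists were not always centred on 0. For WDM-WDO over WDM-CDO, AP-1 genes had a median of −0.01 at the 84.0th percentile. Higher and lower below are therefore relative to random lists. With WD mothers and offspring on CD, AP-1 and early response genes were higher (median 0.23 over 19 genes, 99.9th percentile), as were adhesion and chemokine genes (0.16 over 8, 98.6th), and lymphocyte markers were lower (−0.27 over 8, 0.52th). Of the adhesion and chemokine genes, the neutrophil chemokine genes Cxcl2 (108 against 35 reads, interval 0.58 to 1.68) and Cxcl1 (0.88, 0.25 to 1.51) were higher, as was the early response gene Ier3 (0.97, 0.43 to 1.52), with intervals of counting error. Endothelial identity genes, whose regions were often added in this comparison, had a median of 0.02 over 7 genes with 4 above 0 (88.7th percentile), inside the band. Fibroblast marker regions were also often added in this comparison, 11 of 17 (99.82nd percentile). With WD mothers and offspring on WD, cholesterol export genes were higher (0.35 over 12 genes, 99.99th percentile), including Abca1 (0.66, 0.22 to 1.10) and the lipoprotein receptor gene Scarb1 (0.70, 0.13 to 1.28). In the same comparison 26 of 37 regions near macrophage and monocyte markers were added (99.93rd percentile), and 8 of their gene ends were open in WDM-WDO alone. Endothelial identity genes were lower there (−0.76 over 5, 0.205th), with the angiopoietin coreceptor gene Tie1 at −1.03 (−1.66 to −0.41), as were Notch and angiogenesis genes (−0.28 over 13, 0.71th) and genes of endothelial to mesenchymal transition (−0.25 over 15, 0.66th).

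With the offspring on WD and mothers on CD, 7 lists were higher, in a comparison where 23 of 30 lymphocyte marker regions were lost (above every random list) and 6 of 16 lymphocyte gene ends were open in CDM-CDO alone. They were antigen presentation (0.50 over 13 genes, above every random list), adhesion and chemokine genes (0.56 over 8, 99.98th percentile), AP-1 (0.29 over 17, 99.8th), endothelial identity (0.69 over 5, 99.8th), NF-kB (0.25 over 17, 99.4th), shear stress (0.38 over 6, 99.0th) and oxidative stress genes (0.22 over 12, 98.2nd). Cxcl2 stood at 1.52 (0.95 to 2.09). With the mothers on WD, antigen presentation (0.26 over 15, 99.9th), interferon response (0.39 over 17, 99.7th), fatty acid handling (0.28 over 15, 98.8th) and NF-kB genes (0.13 over 18, 98.6th percentile) were higher. Notch and angiogenesis genes (−0.23 over 13, 1.61th) and endothelial identity genes (−0.24 over 6, 2.36th) were lower, among them Notch1 at −0.94 (−1.37 to −0.50). In the same comparison 23 of 40 macrophage and monocyte regions (99.98th percentile) and 7 of 10 neutrophil marker regions (99.97th) were added, and 20 of 40 lymphocyte marker regions were lost (98.9th).

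Of the 2777 regions in both CDO lists and neither WDO list, 667 were near gene ends, and some lay at far ends of genes or at immunoglobulin genes. At the far ends of genes over 5 kb whose other end was open in all 4 lists, 73 ends were called in both CDO lists alone and 7 in both WDO lists alone, a CDO share of 91.25% (83.0 to 95.7%), against 76.3% (74.7 to 77.9%) away from gene ends. All other gene ends had a share of 91.97% (89.7 to 93.8%). That set still held the far ends of genes under 5 kb and of genes close to others. Its like share therefore cannot decide the matter, and reads made from RNA in the CDO libraries may or may not have a part in the excess. Lymphocytes in the CDO preparations also stay open: lymphocyte marker regions were lost at the 98.65th percentile or higher in both comparisons and their alternatives, but this loss prompted the explanation and so does not test it, and how many members endothelium also expresses was not tested. Regions at immunoglobulin genes numbered 20, 18, 0 and 7 in CDM-CDO, WDM-CDO, CDM-WDO and WDM-WDO, those at T cell receptor genes 20, 26, 2 and 10, and the offspring's diet and the 08w or 12w label, which coincide, stay open and untested.

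The lists of WD mothers held more peaks and more unshared peaks. Whether deeper or more enriched libraries are the cause cannot be told apart by the expected pileups: at least 99.6% of their unshared peaks were expected under 2 times the calling pileup of the other list, against 96.1% and 94.97% for CD mothers, but 1 scaling factor per list (0.685 and 0.637 for WD mothers, 1.41 and 1.48 for CD mothers) brings such an order about by itself. An effect of the mothers' diet on the same regions under both offspring diets was measured by an odds ratio of 1.28, which was 2.09 at equal length and 0.767 with the stricter threshold, so it stays open as well.

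Macrophage and monocyte marker regions were added in WDM-WDO, and at equal list length the percentile was still 99.955 or higher in both comparisons, which argues against the length of this list as the cause. A lower share of endothelial cells would add regions of the other cell types alike, and against WDM-CDO fibroblast marker regions were instead lost (12 of 22, 34.7 to 73.1%, 98.665th percentile), where 5 of 40 macrophage and monocyte regions were (5.46 to 26.1%); on the side of this explanation, 7 of 16 smooth muscle regions were added (23.1 to 66.8%, 94.06th), an interval that overlaps that of macrophages, and neutrophil markers were added too (99.97th), while lymphocyte (20 of 40, 98.9th) and adipocyte marker regions (97.585th) were lost. Against CDM-WDO such a lower share stays open, since smooth muscle and fibroblast losses reached the 76.365th percentile at most, with intervals that overlap those of macrophages, while endothelial identity regions were lost in both comparisons (99.98th and 99.78th) and their pileup ratios were −0.76 against CDM-WDO and −0.24 against WDM-CDO. More macrophages or monocytes in this preparation may account for the pattern, but with 12 of 16 gene ends open (50.5 to 89.8%) against 5 of 16 in the next list (14.2 to 55.6%) the intervals overlap. These intervals ignore that the same 16 genes were counted in each list. Gene by gene, 7 were open in WDM-WDO alone and 0 in WDM-CDO alone, and against CDM-WDO 8 and 0. The pattern prompted this explanation, so these counts do not test it. The strongest gene ends were those of Cd68 (−log10 q of 31.0) and Cd14 (24.7), which were open in all 4 lists and so are no part of the difference; how many members endothelium also expresses and any sort of the cells are not given in the sources used here, and the diets stay open, untested.

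The share of peaks on chromosome X was 3.05% in CDM-CDO (2.83 to 3.28%), 3.09% in WDM-CDO (2.89 to 3.30%), 3.97% in CDM-WDO (3.70 to 4.25%) and 2.22% in WDM-WDO (2.05 to 2.41%), and in the stronger 50% of each list 2.38%, 2.32%, 2.34% and 2.13%. The strongest peak of CDM-CDO (−log10 q of 1011) and of WDM-CDO (814) lay at Cd74 (chromosome 18, 60812153 to 60812615), where CDM-WDO had no overlapping peak.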
